A study of Arabidopsis thaliana with 4 samples.

How the data were processed

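SMXL6 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an anti-HA antibody in whole seedlings of Arabidopsis thaliana aged 2 weeks. There were 4 libraries: 2 from smxl6/7/8 triple mutants carrying SMXL6-HA under the SMXL6 promoter and 2 from the triple mutant without the transgene, used as the control. The labels do not say whether the 2 replicates of a group came from separate cultures, so overlap between replicates measures the spread between these libraries, which may be technical. Per the submitters' processing notes, BWA 0.7.10-r789, SAMtools and MACS 1.4.2 were used with the build TAIR10. Their parameters, the read depth and any removal of duplicate reads are not given in the sources used here. The authors called peaks per replicate, with SMXL6-HA replicate 1 set against control replicate 1 and SMXL6-HA replicate 2 against control replicate 2, per the labels and the deposited files. List 1 and list 2 below are these 2 peak lists. Each row gives a chromosome, a start, an end, a name and a score, and the deposited files give no summit, read count or fold enrichment. The score is the authors' own value per peak. It was taken to be the log-transformed p of the peak caller, because all scores but 1 lay above 50, the value of a p of 1e-05 on that scale. Scores were used to rank, describe and filter peaks within a list. Because depth is unknown, no interval on a single peak could be given, and a gene without a peak may be bound below what these libraries could detect.

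Genes came from a RefSeq gene table of the assembly TAIR10.1, which has the same nuclear chromosome sequences as TAIR10. That table holds names, gene ends and gene types for 37899 nuclear genes, 27444 of them protein-coding. It gives neither strand, exons nor sequence. The planned windows around transcription start sites were therefore replaced by windows at both ends of every protein-coding gene, from 1000 bp outside to 200 bp inside the end. UTR, exon and intron classes were replaced by 3 classes of peak midpoints: inside a gene, outside but within 1000 bp of one, and farther. The planned tests of sequence motifs and 6-mers need the genome sequence and were not run. The match of the builds was checked by moving all midpoints along the chromosomes. The share inside genes was 39.8% for list 2 at offset 0, against 64.9% with midpoints moved by -10000 bp and 63.2% with 10000 bp. Peak coordinates are those of the deposited files on TAIR10, counted from 1. "Below" and "above" a gene mean lower and higher coordinates on the chromosome, since strand was not used here.

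A peak was shared if it overlapped a peak of the other list by at least 1 bp, and shared peaks were taken as list 1 intervals. Overlap was tested with a one-sided permutation test of 100000 circular shifts of list 2 within each of the 5 nuclear chromosomes (for reciprocal overlap the shifts counted overlaps of 1 bp, which makes that p an upper bound). Chromosome length was taken as the largest gene or peak end. Scores of shared and unshared peaks were compared by a two-sided permutation test of the difference of medians (100000 resamples). Positions were tested by circular shifts of the midpoints, with 100000 shifts for the main result and 10000 for alternatives. A target gene had a peak in either end window, and a shared target gene had one in both lists. Fixed gene lists were tested among shared target genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 23 lists, against all nuclear protein-coding genes. Of the 350 symbols in the 14 lists written as symbols, 330 matched by symbol or synonym and 13 by locus code, 5 were ambiguous and 2 were absent. The other lists were 8 transcription factor families and a list of strongly transcribed genes, matched by symbol patterns that were written after the files had been opened. After a first run, 4 family members that share a symbol with another protein were removed, haemoglobins were taken out of the homeobox list, ARF3 was pointed to the auxin response factor, and resistance genes and phosphoserine aminotransferases were taken out of the list of strongly transcribed genes. Family lists hold only genes with such a symbol, so they do not cover whole families.

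The rule for named genes was set before the data were examined. SMXL6, SMXL7, SMXL8, BRC1, TCP1 and PAP1 were always named, from prior knowledge of the study. The 15 shared target genes with the best mean rank of score were named, with 1 gene per peak, the one with the end nearest the midpoint. From each list up to 4 bound members were named by mean rank. MGT9, NIA1, FAD3 and AT3G18535 are named because they lie at a peak near one of these. CKX7 in its comparison with SMXL6 and the members of families and microRNA genes in the closing section were chosen after their values were seen.

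Alternatives set beforehand were reciprocal overlap of 50%, scores of at least 100, uniform placement, exclusion of pericentromeres (2 Mb either side of the gene-poorest 1 Mb), windows of 500 and 2000 bp, whole genes, the nearest gene end, each list alone, and exclusion of the SMXL6 locus. The nearest gene end had no distance limit, so genes with long flanks could gain distant peaks. Exclusion of pericentromeres dropped the peaks there, but the shifts still ran over whole chromosomes. That setting therefore does not test the overlap against chance within the chromosome arms. Shifts of midpoints and of both lists together ran over whole chromosomes as well. Others were chosen after seeing the data: exclusion of the score under 50, list 1 peaks trimmed to the median width of list 2, list 1 limited to as many peaks as list 2, shared peaks taken from list 2, exclusion of the SMXL6 locus from target genes, circular shifts of both lists together, and controls matched on the length of intergenic flanks. The overlap and list tests were tested on simulated data. In 20 simulated pairs of lists all 500 planted shared peaks were found, and unplanted peaks overlapped by chance 73.3 times on average, against a mean of 70.9 over the shifts. Of 100 simulated lists of 40 genes with 30% of members seeded among the targets, 100 were called, and of 360 unseeded lists 0 were called. Simulated targets and list members were single genes drawn at random, without neighbours at the same peak and without regard to flank length. These counts therefore do not give the rate of false calls in the real lists. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.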

Results

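SMXL6, SMXL7 and SMXL8 are related repressors of strigolactone signalling that are degraded when the hormone is perceived. The series asked where SMXL6 sits on chromatin in seedlings. Plants lacking all 3 repressors and carrying SMXL6 tagged with HA under its own promoter were compared with the same mutant without the transgene, so anti-HA signal in the control is background. Each of the 2 replicate pairs gave a list of peaks called against its control. List 1 held 1789 peaks with a median width of 2824 bp, covering 5.63 Mb, and list 2 held 1442 peaks with a median width of 1236 bp, covering 2.03 Mb. The score given with each peak is the authors' own value. The median score was 92.0 in list 1 and 89.2 in list 2. Read depth is unknown.

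The first question was whether SMXL6 occupied the genes of its own family. The highest-scoring peak of both lists lay over SMXL6 itself. It spanned chromosome 1, 2208457 to 2215717, in list 1 and 2208640 to 2215505 in list 2, with a score of 3100 in each, a value no other peak reached. The same value in both lists may be a ceiling of the score, so it was not read as equal signal. These peaks covered 100% and 96.2% of the gene and ran on for 2999 bp and 2787 bp above it. The transgene adds SMXL6 sequence that the control plants lack, so this locus is not comparable with the rest of the genome. SMXL7 had a peak over its lower end in each list, at chromosome 2, 12775487 to 12777402 (score 149.56) in list 1 and 12775713 to 12777225 (score 149.75) in list 2. A further list 1 peak lay 881 bp below the gene, with a score of 59.72. Above SMXL7, list 1 had a peak 741 bp away with a score of 233.75 that covered the whole of FAD3. List 2 had a pair there with scores of 57.01 and 54.97, the first over the lower end of FAD3 and the second inside it. FAD3 had the nearest gene end to each of these peaks, so they were not read as peaks of SMXL7. At SMXL8, peaks over the lower end stood at chromosome 2, 16763665 to 16766480 in list 1 and 16764752 to 16765984 in list 2. The list 1 score was 116.5, rank 648. The list 2 score was 20.72, the lowest of that list and its only score under 50, so SMXL8 counted as shared only with that peak included.

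BRC1, a TCP transcription factor that holds back bud outgrowth, had no peak within the 1000 bp window, but a high-scoring shared peak lay just beyond it. It spanned chromosome 3, 6379829 to 6382025, in list 1 (score 942.69, rank 5) and 6380157 to 6381829 in list 2 (score 1051.69, rank 9). Its edge was 1264 bp and 1460 bp below the gene, and BRC1 had the nearest gene end in both lists. A second shared peak, with scores of 296.09 and 327.12, overlapped AT3G18535, the gene with the nearest end to it in both lists, 4467 bp and 4876 bp below BRC1. With windows of 2000 bp, or with each peak given to the gene with the nearest end, BRC1 was a shared target gene. TCP1 had no peak within 10000 bp in either list. At PAP1, a MYB activator of anthocyanin synthesis, the only peaks within 5000 bp lay 4509 bp and 4861 bp below the gene, with scores of 115.57 and 136.25. PAP1 was not a target gene under any window tried.

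**Figure D1:**
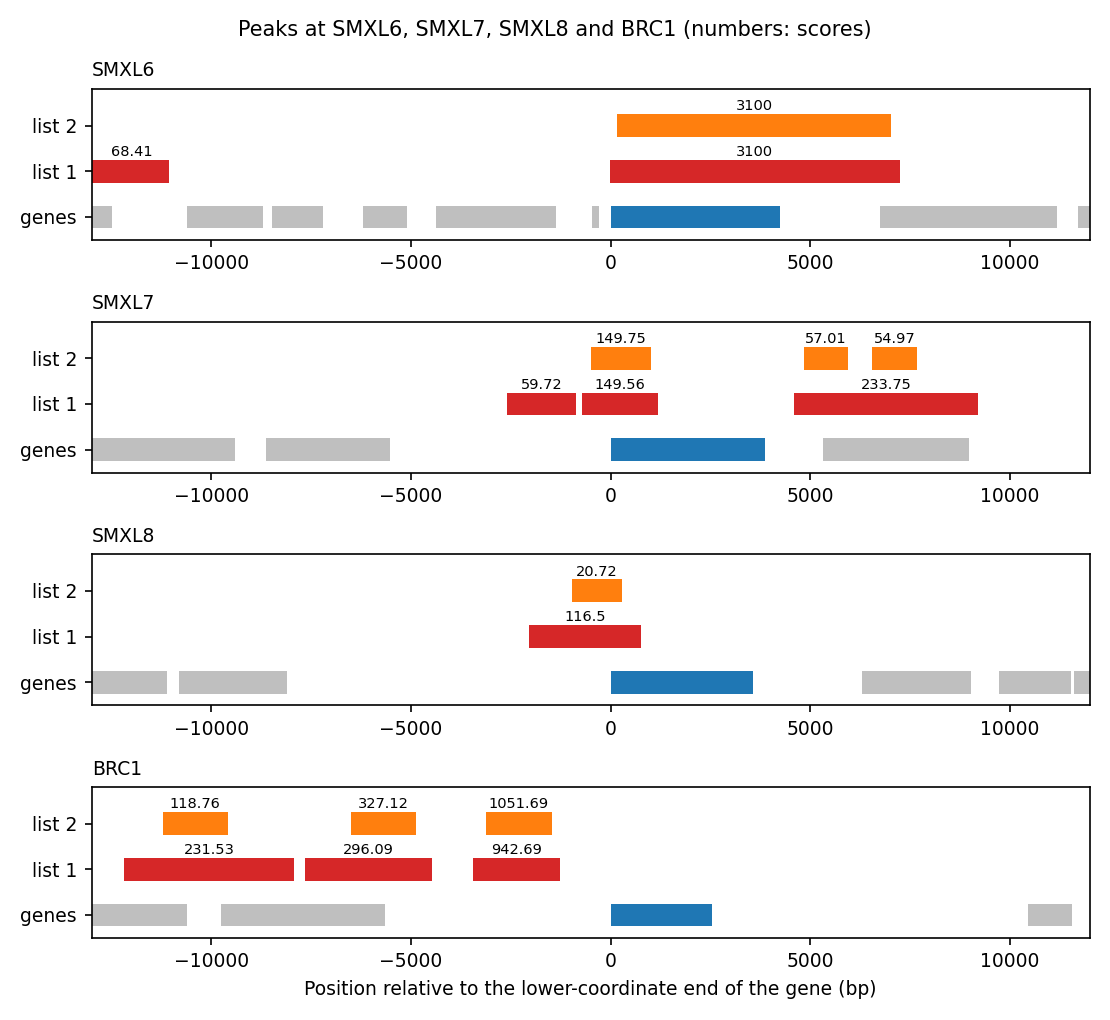
Maps of the peaks of list 1 (red) and list 2 (orange) around SMXL6, SMXL7, SMXL8 and BRC1. The horizontal axis is the distance in bp from the lower-coordinate end of the named gene (blue), other protein-coding genes are grey, and the numbers are peak scores, up to 3100 over SMXL6 and 942.69 and 1051.69 below BRC1.

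The second question was how far the replicate lists pointed to the same sites. Of the list 1 peaks 982 (54.9%) overlapped a list 2 peak, and of the list 2 peaks 1077 (74.7%) overlapped a list 1 peak. Shifted lists gave 92.5 overlapped list 1 peaks on average and 358 at most. The observed number was 10.6 times that mean (one-sided permutation test, p = 1e-05, the smallest the shifts can give). Requiring overlap over 50% of both peaks left 483 shared peaks, 5.22 times the mean of shifts counted at 1 bp. Scores of at least 100 left 427, 19.6 times the mean of their shifts. List 1 peaks trimmed to the median width of list 2 gave 917, 16.3 times the mean. Peaks differed in width. In the 892 pairs in which 1 peak of each list overlapped only the other, the median width was 2786.5 bp in list 1 and 1278.5 bp in list 2, and in 95.1% of pairs the list 2 peak lay wholly inside the list 1 peak.

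Shared peaks had higher scores than unshared ones. The medians were 122 against 70.4 in list 1 and 106 against 69.5 in list 2 (two-sided permutation test within each list, p = 2e-05, the smallest it can give). The size of the difference depended on the setting. With reciprocal overlap of 50% the list 1 medians were 115 against 85.4. With scores of at least 100 the list 2 medians were 212 against 129. The share of overlapped peaks rose with the score, from 29.3% in the lowest 25% of list 1 to 86.8% in the highest, and from 56.2% to 95.8% in list 2. Of the 100 highest peaks, 96 in list 1 and 98 in list 2 were shared. Fewer, 61 of the 100 highest in list 1, overlapped a peak among the 100 highest in list 2. Across the 982 shared peaks, which are not independent replicates, scores in the lists were correlated, with Pearson's r of 0.836 and Spearman's rho of 0.602 (two-sided permutation p = 2e-05 for each, the smallest it can give). Without the 2 peaks farthest from the median list 1 score, r was 0.771, and without the SMXL6 locus it was 0.798. These were 2 coefficients on 1 relation, and adjustment over them leaves both p-values as they are.

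**Figure D2:**
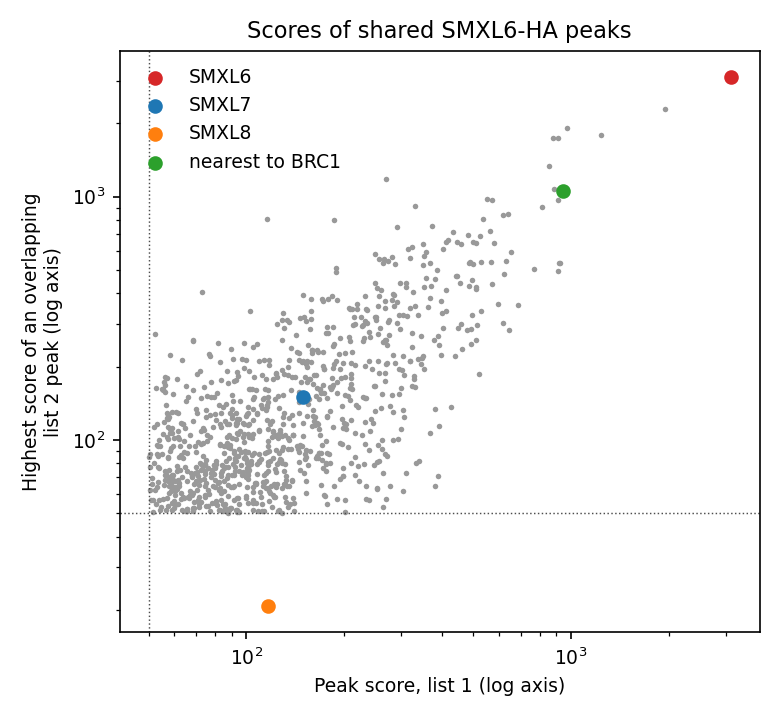
Scores of the 982 shared peaks, 1 grey point per list 1 peak, with its list 1 score on the horizontal axis and the highest score of an overlapping list 2 peak on the vertical axis, both on log scales without units. Coloured points mark the peaks over SMXL6, SMXL7 and SMXL8 and the peak nearest to BRC1, dotted lines mark a score of 50, and the SMXL8 peak, at 20.72 in list 2, lies under it.

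Relative to shifted positions, midpoints of shared peaks were more frequent just outside genes and less frequent inside them. Of the 982 midpoints, 363 (37.0%) lay outside protein-coding genes but within 1000 bp of one, against a mean of 20.4% over shifted positions (SD 1.39; two-sided permutation test, p = 2e-05, the smallest it can give). Midpoints inside genes made up 43.5%, below the 54.3% of shifted positions (SD 3.3, permutation p = 0.0002). Midpoints farther away made up 19.6%, against 25.3% (SD 3.61, permutation p = 0.119). With the limit at 2000 bp this class made up 8.86%, against 17.9% (permutation p = 0.007). With 500 bp it made up 33.5%, against 32.5% (permutation p = 0.808). The shifts ran over whole chromosomes, while 1763 of the 1789 list 1 peaks lay outside pericentromeres. Differences from shifted positions therefore mix placement relative to genes with scarcity of peaks in pericentromeres. With list 1 midpoints moved by only -10000 bp and 10000 bp, 61.7% and 63.0% lay inside genes, against 46.4% unmoved. The lower share inside genes thus also held against nearby positions. The median distance from a midpoint to the nearest gene end was 540 bp. Which end was the promoter could not be told, since strand was not used here.

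Genes with a peak at either end numbered 3089 in list 1 and 1834 in list 2, and 1384 were shared target genes, 5.04% of protein-coding genes. Independent lists would share 206 (odds ratio 43.1, Fisher's exact test, two-sided, with a p-value too small for the software to represent). Circular shifts of both lists together gave 1175 shared target genes on average and 1427 at most (permutation p = 0.0022). The odds ratio therefore measures agreement between the lists, not placement of peaks at genes, and genes at the same peak were counted separately. The shifts crossed pericentromeres too, so their p does not test placement at genes within the chromosome arms. Assigning each peak only to the gene with the nearest end gave 854 shared target genes, and scores of at least 100 gave 592.

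After SMXL6, the highest-ranked target was AT5G64550, whose peak at chromosome 5, 25804434 to 25807410 in list 1, also lay at MGT9, a magnesium transporter gene. Its scores were 1949 and 2301.27. A/N-InvC, an alkaline/neutral invertase, followed with scores of 971.14 and 1908.17. Transcriptional regulators among the 15 named by rank were GATA1 (885.08 and 1072.46), CBF1, a cold-response activator (857.61 and 1332.03), TCP9 (550.61 and 976.62), the auxin repressor IAA9 (534.77 and 812.97) and LBD37, a regulator of nitrogen-responsive genes (653.92 and 593.35). ACR8 had scores of 911.44 and 967.15, CAT6, a cationic amino acid transporter, 641.39 and 849.64, RABA1d, a small GTPase, 572.13 and 969.62, and SHOT1 618.35 and 841.29. The others were AT5G08139, AT3G50800 and AT1G77750, and the peak of the last also lay at NIA1, which encodes a nitrate reductase. Only shared target genes were ranked. A shared peak with scores of 1239.49 and 1800.11, and the peak nearest to BRC1, belonged to none of the 15.

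Of the 23 fixed gene lists, 11 passed the threshold, among them light and clock, brassinosteroid, abscisic acid, cytokinin and auxin genes. In the light and clock list 11 of 32 members were shared target genes, against 1.61 expected (odds ratio 9.93, Fisher's exact test, adjusted p = 5.74e-06). They included LUX, a component of the evening complex (scores 190.28 and 377.53), PIF7 (428.03 and 136.53), PIF5 (172.59 and 228.79) and LHY (184.26 and 168.61). In the brassinosteroid list 7 of 16 were bound (odds ratio 14.7, adjusted exact p = 7.19e-05): BEE1 (268.6 and 205.77), the biosynthetic gene DWF4 (219.97 and 136.36), the kinase gene BIN2 (165.22 and 163.76) and BEE3 (270.99 and 85.85) ranked highest. In the abscisic acid and drought list 10 of 41 were bound (odds ratio 6.11, adjusted exact p = 0.000178), among them the receptor gene PYL9 (444.68 and 653.3), RD26 (361.72 and 350.73), the phosphatase gene ABI1 (125.98 and 134.6) and CYP707A2, which encodes an enzyme of abscisic acid breakdown (171.09 and 82.36). With scores of at least 100 this list no longer passed (adjusted exact p = 0.112, the highest of a range from 4.34e-06 over the alternatives).

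In the cytokinin list 7 of 39 were bound (odds ratio 4.13, adjusted exact p = 0.00777), including the cytokinin oxidase genes CKX7 (500.34 and 653.85), CKX6 and CKX5 and the activating enzyme gene LOG8 (235.59 and 301.2). In the auxin list 8 of 66 were bound (odds ratio 2.61, adjusted exact p = 0.0404), with IAA9, the efflux carrier gene PIN3 (324.08 and 275.8), ARF2 (521.32 and 187.27) and IAA26 (295.58 and 154.17). The auxin list did not pass when list 1 peaks were trimmed to the median width of list 2 (adjusted exact p = 0.329, the highest of a range from 6.15e-06 over the alternatives), nor against genes matched on flank length (adjusted permutation p = 0.188). Of 26 jasmonate genes 4 were bound, all of them JAZ repressor genes: JAZ6 (444.55 and 473.67), JAZ1 (367.86 and 382.65), JAZ5 (158.2 and 208.41) and JAZ9 (113.36 and 71.39). That list did not pass (odds ratio 3.43, adjusted exact p = 0.0652), but it passed with list 2 alone (8 of 26, odds ratio 6.23, adjusted exact p = 0.000790), list 1 alone (0.0384), the nearest gene end (0.0124) and windows of 500 bp (0.0480), in a range up to 0.192 over the alternatives. The gibberellin list had 1 of 18 bound, the receptor gene GID1B (328.72 and 183.73; odds ratio 1.11, adjusted exact p = 0.753). With the nearest gene end it had 5 of 18 (odds ratio 12.04, adjusted exact p = 0.000450) and with windows of 2000 bp 4 of 18 (0.0488), in a range up to 0.753 over the alternatives. The ethylene list had 1 of 21 bound, EBF2 (139.54 and 57.48; adjusted exact p = 1).

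TOPLESS corepressors, which repress transcription when recruited by other proteins, had 4 of 5 genes bound (odds ratio 75.5, adjusted exact p = 0.000178). These were TPR1 (233.77 and 344.4), TPL (206.58 and 264.99), TPR3 (170.94 and 380.5) and TPR2 (116.69 and 160.51). In the SMXL family 4 of 8 were bound (odds ratio 18.9, adjusted exact p = 0.00147): SMXL6, SMXL7, SMXL8 and SMXL2 (290.86 and 301.77). This list holds the transgene's own locus and genes picked from knowledge of the study, so it is not independent evidence. Without the SMXL6 locus 3 of 8 were bound (odds ratio 11.3, adjusted exact p = 0.0150), as without the score under 50 (0.0151), and with list 1 alone the odds ratio was 7.89 (adjusted exact p = 0.0177, the highest of a range from 0.000194 over the alternatives). No setting left out SMXL6 and SMXL8 together, which would leave only SMXL7 and SMXL2 bound. Whether the list would pass without both was not tested. The other strigolactone and karrikin pathway genes had 1 of 11 bound, the karrikin receptor gene KAI2 (77.05 and 102.49; adjusted exact p = 0.624). Shoot branching genes had 1 of 13, NCED3, which encodes an enzyme of abscisic acid synthesis (88.45 and 84.07; adjusted exact p = 0.663). Windows of 2000 bp, which take in BRC1, brought the branching list past the threshold (adjusted exact p = 0.0201), as did the nearest gene end, and values ranged from 0.0112 to 1 over the alternatives. The branching and anthocyanin lists, too, hold genes named from knowledge of the study. Of 19 genes for anthocyanin regulation and synthesis 0 were bound, against 0.958 expected (adjusted exact p = 0.753). With windows of 2000 bp 3 of 19 were bound (odds ratio 2.54, adjusted exact p = 0.177), as were 3 of 19 with list 1 alone (odds ratio 1.48, adjusted exact p = 0.511). The list passed in no setting.

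Of the transcription factor families, the ERF, DREB and CBF family had 10 of 47 members bound (odds ratio 5.12, adjusted exact p = 0.000444). CBF1, CBF2 and DREB1A are neighbours. CBF2 and DREB1A had the same highest list 1 peak, with a score of 331.73, and separate list 2 peaks with scores of 345.1 and 356.68. CBF4 had scores of 188.63 and 507.5. The SPL family had 5 of 16 (odds ratio 8.59, adjusted exact p = 0.00264), including SPL8 (256.97 and 556.28), SPL1 (212.61 and 297.41) and the neighbours SPL10 and SPL11, which shared a list 1 peak. Adjusted over 158 symbol families, a scan chosen after seeing the data, the SPL family did not pass (adjusted exact p = 0.0663), nor did genes with an ERF symbol (0.0663) or an HB symbol (0.656). Homeobox genes had 9 of 51 (odds ratio 4.05, adjusted exact p = 0.00264), among them HAT2 (439.97 and 221.92), HB5 (185.75 and 799.83), HAT3 (208.81 and 162.76) and HB-1 (199.45 and 117.33). With scores of at least 100 neither family passed (adjusted exact p = 0.0955 for SPL and 0.0554 for homeobox genes, the highest of ranges from 0.000226 and 9.13e-07 over the alternatives). TCP factors had 4 of 22, TCP9, TCP21 (209.84 and 120.71), TCP7 (126.93 and 83.38) and TCP22 (59.39 and 62.24), at the edge of the threshold (odds ratio 4.19, adjusted exact p = 0.0476). The symbols TCP11 and TCP21 matched the same gene, so a TCP gene may be missing from the 22, and TCP factors might not pass with it. They were also sensitive to the setting. TCP factors did not pass with circular shifts of both lists (adjusted permutation p = 0.0510) or against genes matched on flank length (adjusted permutation p = 0.183), and exact values ranged from 0.00767 to 0.143 over the alternatives.

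WRKY genes (8 of 72, led by WRKY22 with 567.29 and 538.28; adjusted exact p = 0.0541), NAC genes (10 of 100, led by NAC062 with 349.56 and 639.34; adjusted exact p = 0.0619) and MYB genes (7 of 125, led by MYB102 with 461.8 and 236.1; adjusted exact p = 0.785) did not pass. With the nearest gene end all of these did: MYB genes had 12 of 125 bound (odds ratio 3.34, adjusted exact p = 0.00113), WRKY genes 9 of 72 (4.48, p = 0.000889) and NAC genes 8 of 100 (2.72, p = 0.0185). MYB genes also passed with windows of 2000 bp (adjusted exact p = 0.0488) and list 1 alone (0.0203), and NAC genes with windows of 2000 bp (0.0463) and list 2 alone (0.0420). The highest values over the alternatives were 0.962 for MYB, 0.354 for WRKY and 0.409 for NAC genes. Genes with a bHLH symbol (1 of 22, the iron-response gene FRU with 51.91 and 113.15; adjusted exact p = 1) and ZAT zinc finger genes (1 of 5, RHL41 with 155.31 and 244.87; adjusted exact p = 0.350) did not pass. ZAT genes passed with list 1 alone (3 of 5, odds ratio 11.8, adjusted exact p = 0.0229, the lowest of a range up to 0.396 over the alternatives). Strongly transcribed genes, a check on unspecific capture, had 8 of 192 bound, against 9.68 expected (odds ratio 0.818, adjusted exact p = 0.810). The highest-ranked were AT1G77750, TUB5 (287.79 and 526.04), LHCB4.3 (149.5 and 392.49) and PRPL35 (157.13 and 286.46).

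**Figure D3:**
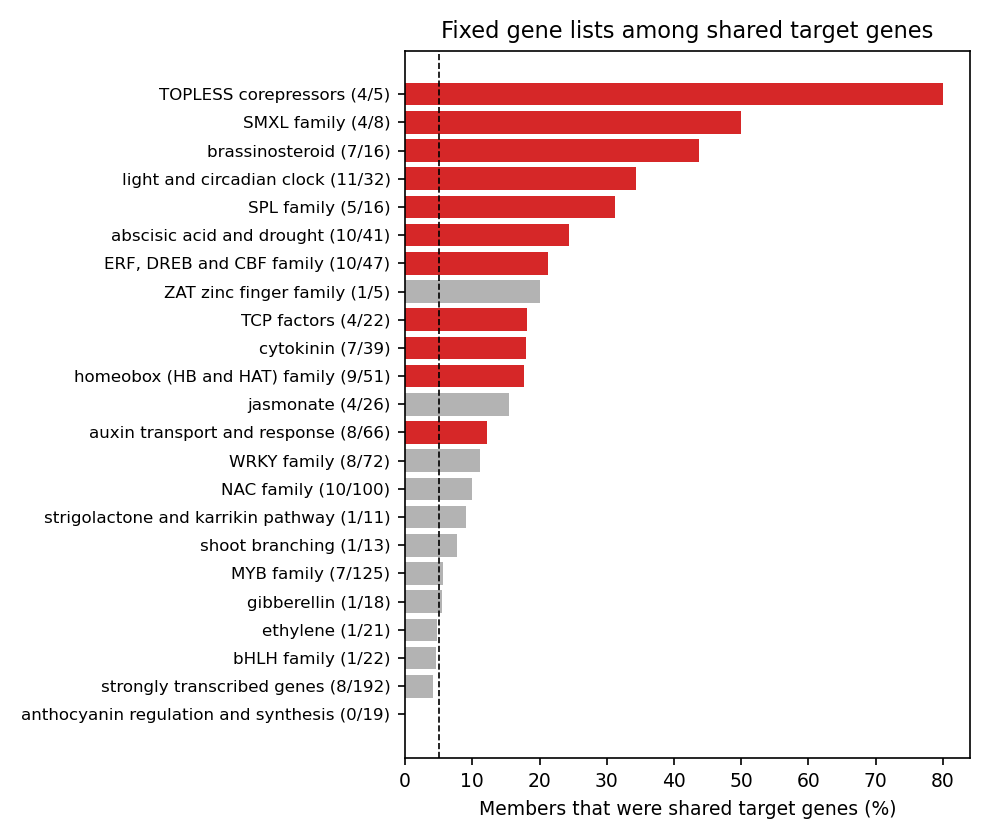
Percentage of the members of each fixed gene list that were shared target genes, with the numbers bound and tested after each name. Red bars mark the 11 lists with an adjusted p under 0.05 by Fisher's exact test, and the dashed line marks the 5.04% of all protein-coding genes, which the 80% of TOPLESS corepressors and 34.4% of light and clock genes exceed.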

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

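None of the results past a threshold changed direction under the alternatives that were run, and the count of shared peaks passed its test under all 7 (permutation p = 1e-05 for each). The counts themselves moved in places. Shared peaks numbered 483 with reciprocal overlap of 50% and 427 with scores of at least 100, both by construction fewer. Shared target genes numbered 854 with the nearest gene end and 592 with scores of at least 100, where fewer gene and peak pairs qualify. Lists past the threshold numbered 17 with the nearest gene end and 7 with scores of at least 100, and the cause was not tested. Of the 11 lists, 6 passed in all settings, planned and added after seeing the data, that reran Fisher's exact test: TOPLESS corepressors, the SMXL family, the ERF, DREB and CBF family, brassinosteroid, cytokinin, and light and clock. For the SMXL family, none of these settings left out SMXL6 and SMXL8 together. The jasmonate, NAC, MYB, WRKY, ZAT, gibberellin and shoot branching lists passed in some of these settings but not in the main one. Peaks within 5000 bp of SMXL8 numbered 1 without the score under 50, an exclusion chosen after seeing the data, as it removes 1 of 2. With a single replicate list in place of shared peaks, midpoints inside genes ranged from 39.8% to 46.4%, midpoints within 1000 bp of genes from 34.4% to 39.7%, and lists past the threshold stood at 13 for either list. TCP factors were lost with list 1 alone. The planned motif and 6-mer alternatives (central 200 bp, shuffled sequence, GC matching, stricter score, each list alone) were not run, since no genome sequence was used here. No paired analysis was possible because peaks were called per replicate pair and no test across libraries was made. Read depth is unknown, so how many sites either replicate missed could not be estimated.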

Other observations

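The settings with the nearest gene end and with each list alone were planned, and the other tests in this part, with the scans of families and microRNA genes, were chosen after seeing the data; for the flanks of all 11 lists and for the width of high-scoring peaks, what would count for or against was written before the results of those tests were seen, and for the others after.

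A scan of all 158 families of at least 10 protein-coding genes with a common symbol found none past the threshold after adjustment, by Fisher's exact test or by shifting both lists together. Unadjusted, 12 had a p under 0.05 by the exact test and 11 by the shifts. The lowest p-value belonged to EMB genes, named for embryo lethality when mutated. Of 160 such genes 0 were shared target genes, against 8.07 expected (Fisher's exact test, two-sided, p = 0.000416, adjusted p = 0.0657). SPL genes had 5 of 16 bound (adjusted exact p = 0.0663), so their call over the 23 fixed lists is lost over the 158 families. Parts of other called lists did not pass here either: genes with an ERF symbol had 6 of 25 bound (adjusted exact p = 0.0663) and genes with an HB symbol 5 of 41 (adjusted exact p = 0.656). BBX zinc finger genes had 5 of 20 bound (BBX8, BBX14, BBX15, BBX28 and BBX29; odds ratio 6.30, adjusted exact p = 0.105), and trehalose-phosphate or terpene synthase genes under the symbol TPS had 4 of 19 (TPS7, TPS8, TPS9 and TPS11; adjusted exact p = 0.268). Of 326 microRNA genes 9 had a peak at an end in both lists, among them MIR156h, MIR159b, MIR167a and MIR168a, against a mean of 10.4 over shifts of both lists (two-sided permutation test, p = 0.852).

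The lists past the threshold included light and clock, brassinosteroid, cytokinin and TOPLESS genes but not all hormone lists, and the jasmonate and gibberellin lists passed only in some settings (lowest adjusted exact p = 0.000790 and 0.000450). The share of shared target genes was 2.19% in the 10% of genes with the shortest flanks, 7.35% in the 10% just short of those with the longest, and 5.43% in the 10% with the longest, but 9 of the 11 lists kept an adjusted p under 0.05 in a permutation test against random genes matched on flank length, which argues against flanks for these 9. For the same 9, wide list 1 peaks reaching neighbouring genes are argued against, as all 9 passed with list 1 peaks trimmed to the median width of list 2. For these 9, what would count had been written for the nearest gene end and not for trimming. With the nearest gene end 11 of the 11 lists passed, but that setting has no distance limit. Genes with long flanks can then gain distant peaks, so it is no separate support. The SMXL family is among the 9 with SMXL6 and SMXL8 included, with matched flanks and with trimmed peaks alike. The list of strongly transcribed genes was picked by symbol, without expression data. The upper 95% limit of its odds ratio, 1.65, lay under the lowest of a list past the threshold, 2.61. That argues against general capture of such genes, but transcription of the 9 lists was not measured here. The auxin list and TCP factors, near the threshold from the start, were both lost with matched flanks. Their bound over expected members only moved from 2.40 to 2.01 and from 3.61 to 3.07. With trimmed peaks 0 of them passed (odds ratios 1.89 and 3.64). Both passed with the nearest gene end (odds ratios 7.00 and 6.95), but that setting was not matched on flank length. The settings on peak width thus point both ways, and flank length and peak width stay open for these lists. Chromatin accessibility, which was not measured here, stays open for all 11, so direct regulation of these genes by SMXL6 is a hypothesis.

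The peak over the whole SMXL6 gene has a candidate explanation in extra copies of the SMXL6 locus, since the SMXL6-HA plants carry a transgene that the control lacks. List 2 peaks covered 96.2% of SMXL6, against a median of 9.60% over 394 other shared target genes of at least 3000 bp, and 1 of these, CKX7, was covered as far. The other explanation, width that comes with a high score, was not excluded: the widest of the 20 next highest list 2 peaks measured 4348 bp, against 6866 bp at SMXL6. In list 1, 24 of the 394 (6.09%) were covered over their whole length (100%), as SMXL6 was. Extra copies and binding of SMXL6 at its own locus cannot be told apart here, because CKX7 shows that a peak can cover a long gene without a transgene.

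The list 2 score of 20.72 at SMXL8 stood apart from all other scores. A lower score cutoff for list 2 is argued against, because 0 other list 2 peaks had a score under 50 while 257 had one from 50 to 60. Of the 354 list 1 peaks with scores from 100 to 150, as at SMXL8, 221 (62.4%) had a list 2 peak, and apart from SMXL8 the lowest score of such a peak was 50.19. How a peak with this score came to be in the list stays open, and no biological explanation was tested. Target status of SMXL8 in list 2 rests on this peak alone.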
